A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

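Capped 5′ ends of RNA were measured by CAGE, cap analysis of gene expression, in 8 libraries of budding yeast strain BY4741, a laboratory strain of mating type a with defects in HIS3, LEU2, MET17 and URA3. Each strain carried a synthetic copy of the human HPRT1 locus (synHPRT1) or its sequence reversed without complementing it (synHPRT1R), either on a yeast artificial chromosome (YAC) or integrated in the genome. The 4 groups held 2 libraries each. Per the labels' protocols, YAC strains were grown in SC-Leu and integrated strains in YPD, so that context and medium cannot be told apart. Cultures were grown at 30 °C, diluted to an OD of 0.1 and collected after 6 h at an OD near 0.6. Libraries were made from 5 µg of RNA with 20 PCR cycles. No molecular identifiers are mentioned, so intervals printed here cover counting error only. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

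Per the submitters' processing notes, bcl2fastq 2.20, Bowtie2 2.2.9, SAMtools 1.9, deepTools 3.5.0 and MACS2 2.1.0 were used with build sacCer3, and which step each tool served is not given in the sources used here. The authors deposited 32 peak lists, 4 per library, made for each strand against 2 references. In one reference the synthetic sequence with its vector was a contig of its own. In the other it stood inside chromosome XI. Peaks were listed per library, not on pooled libraries. The deposited fold enrichment is a ratio of summit signal to background, and the deposited −log10 columns hold a p-value and a q-value per peak. The deposited score column is 10 times the −log10 q value with its decimals dropped and was not used. These values belong to the peak, are the authors' own, and served here only to rank or filter peaks within a list. The lowest deposited −log10 q was 1.30, and no interval was listed more than once.

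Read totals are not in the files used here, so the depth of a library is unknown as a count. The fold and p of each peak follow a Poisson model of summit pileup over background, from which the pileup was solved. It came out whole within 0.1 for 97.7% to 99.5% of the peaks of a list. The genome-wide background of a list, in tags at a position, lay between 41.0 and 94.8, and the weakest peak of a list stood 1.32 to 1.49 times above it. The fold never exceeded 49.99, which narrows the range among the strongest peaks. In addition, the fold is understated where neighbouring DNA carries many tags.

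Native DNA was the 16 nuclear chromosomes of the same assembly, 12071326 bp in all, with 6002 protein-coding genes in its annotation. A peak was 1 interval on 1 strand. A gene had a start peak when a peak on its strand overlapped the window from 300 bp upstream to 100 bp downstream of its 5′ end. Windows covered 9.88% of strand bases. The forward lists were taken as plus-strand transcription because that orientation placed 2372 to 2650 peaks of a library in such windows, against 589 to 666 for the opposite one. The synthetic denominator ran from position 1 to the largest peak end on the contig. Matching peaks between the references placed the insert, 100578 bp long, after position 146350 of chromosome XI, and the rest of the contig was taken as vector. This assumes that no native DNA was removed on integration.

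Densities were compared as log2 ratios with exact two-sided sign-flip or label permutation tests. With 8 libraries the smallest sign-flip p is 0.00781, with the 4 libraries of a sequence it is 0.125, and 4 libraries against 4 (70 arrangements) cannot go below 0.0286. Genes were compared between groups by presence or absence of a start peak, with Fisher's exact test, Benjamini-Hochberg adjustment and the 35 splits of the libraries. A set of 25 gene lists and the rule for named genes were chosen before the data were examined. The rule names a fixed native reference list, up to 10 synthetic peaks per sequence called in all 4 libraries by highest median percentile of fold, up to 15 genes per direction present in 4 of 4 against 0 of 4 libraries, up to 4 such genes of each list, the auxotrophy and mating-type genes and genes within 5 kb of the insertion point. Of the list symbols, 1 had no match in the annotation. Alternatives covered the q threshold, equal list lengths, covered bases, the other reference, chromosome XII, the gene-start window, bins of 2 kb and covered bases for the mirrored profiles, the overlap that counts as shared, the background of the list test, a replicate block and each library left out in turn. For native peak regions, those sharing at least 50% of their 31-base words were also counted once.

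The functions were tested on simulated data for the gene comparison. All 200 planted genes among 6002, set to be present in 1 group alone, were separated, along with 9 others. All 500 simulated pileups, made with the formula that was solved, were recovered. Both outcomes check the code and do not measure sensitivity in the real lists. Simulated data without a difference gave a p at or under 0.05 in 2.9% of permutation tests and 4.9% of sign-flip tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The sequences of the synthetic constructs were not used here, and mitochondrial peaks were left out of all densities.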

Results

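CAGE peaks were listed for 8 yeast libraries, 2 each of synHPRT1 on a YAC, synHPRT1 integrated, synHPRT1R on a YAC and synHPRT1R integrated. HPRT1 encodes a human purine salvage enzyme, and the synthetic sequences hold its locus in forward or reversed order. The libraries held 2995 to 3367 native nuclear peaks and 86 to 118 peaks on the synthetic contig. In each library 2393 to 2665 of 6002 protein-coding genes had a start peak, 39.9% to 44.4% of all genes. Of these genes, 1239 had one in all 8 libraries and 2029 in none. Gene starts held 75.7% to 79.8% of native peaks. The read depth of the libraries is unknown as a count.

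The first comparison asked whether the synthetic sequences are transcribed in yeast and how they compare with the rest of the genome. Both carried peaks on both strands, and the longest stretch of insert without a peak measured 3645 to 5823 bp over the libraries. The contig held 0.88 ± 0.0965 peaks per kb (SD, n = 8), against 0.258 ± 0.0102 on native chromosomes. The mean log2 ratio was 1.76 ± 0.19 (SD, n = 8), a 3.40-fold higher density, and it was above 0 in 8 of 8 libraries (exact two-sided sign-flip p = 0.00781, the smallest 8 libraries can give). For synHPRT1 the log2 ratio was 1.77 ± 0.17 and for synHPRT1R 1.75 ± 0.23 (SD, n = 4 each; exact p = 0.125 for each, the smallest that 4 libraries can give). Against native DNA outside gene starts the density was 14.2-fold higher, with a range of 11.7 to 18.5 over libraries (exact p = 0.00781, n = 8). None of the 98 native windows as long as the contig reached its density in any of the 8 libraries.

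**Figure D1:**
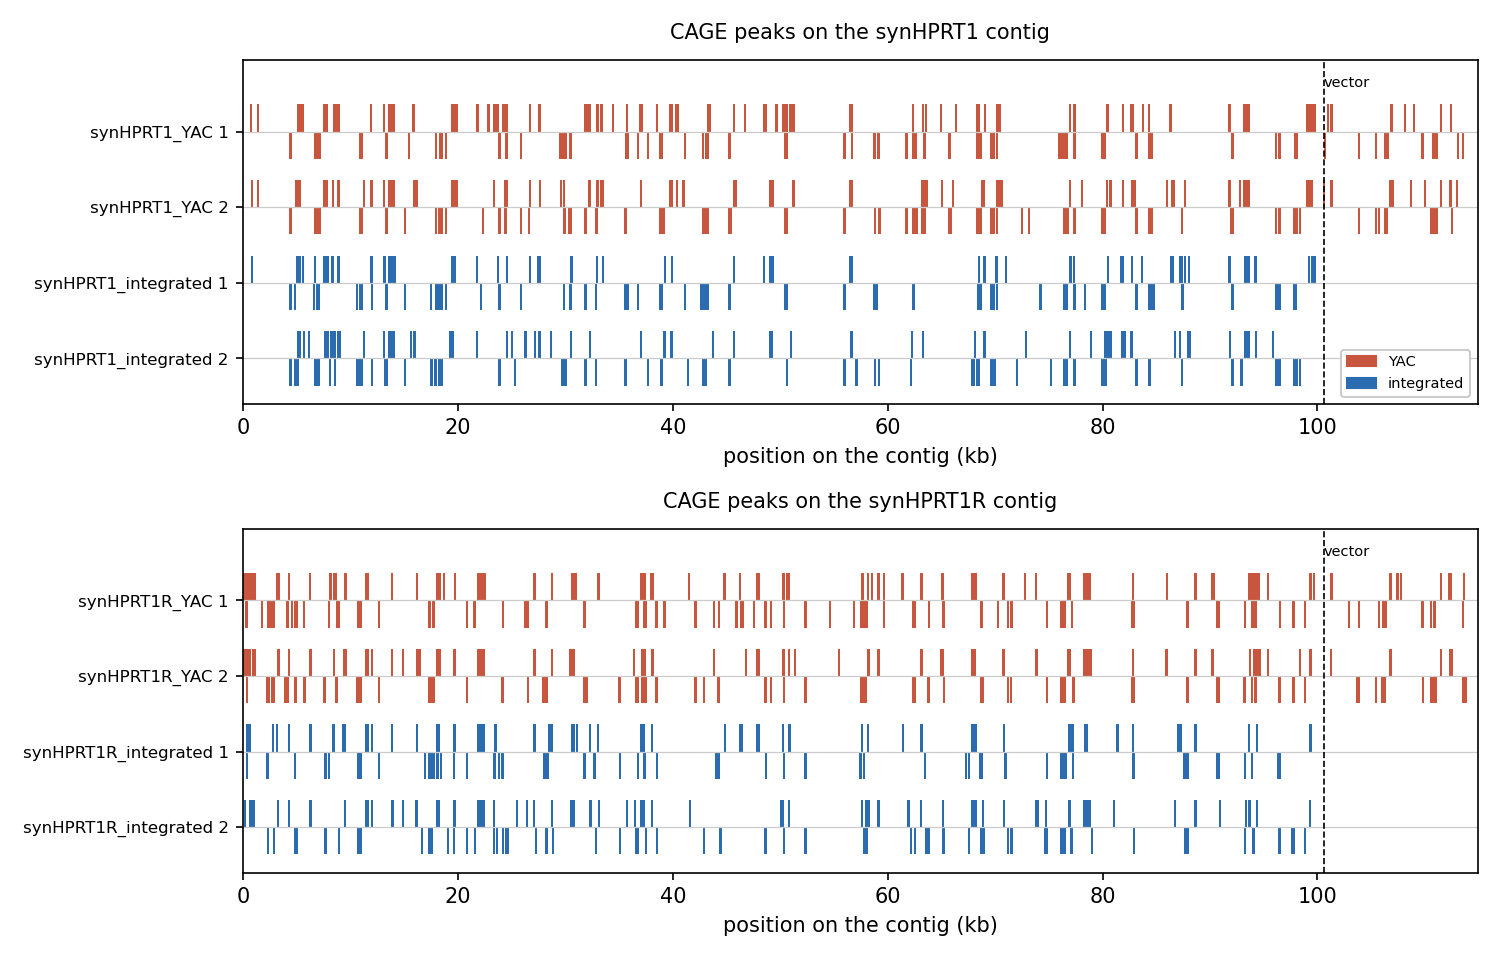
CAGE peaks along each synthetic contig (x axis, position in kb), with 1 row per library, plus-strand peaks above the line, minus-strand peaks below it, and a dashed line at the inferred start of the vector. Peaks are spread along the insert in all 8 libraries, where 23.4% to 29.9% of it lies in a peak on either strand, and the vector part holds 10 to 15 peaks in YAC libraries and 0 or 1 in integrated libraries.

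Named peaks were taken from insert regions with a peak in all 4 libraries of a sequence. On synHPRT1, 43 of 139 strand-specific insert regions had a peak in all 4 libraries, and on synHPRT1R 53 of 141. A peak in 1 library only was found at 45 regions of synHPRT1 and 44 of synHPRT1R. The highest fold of a list was 49.94 to 49.99, so folds near that ceiling do not order peaks by strength. The first of synHPRT1 by percentile of fold lay on the plus strand at contig positions 56404 to 56745. It had a median fold of 49.3 (range 47.6 to 49.5), at the median percentile 98.2 of native peaks. A minus-strand region at 50346 to 50737 had a median fold of 47.6 and percentile 96.5. On synHPRT1R the first by that rank was a minus-strand region at 52154 to 52453, with a median fold of 31.9 and percentile 90.9. It was followed by a plus-strand region at 88539 to 88803 with a median fold of 35.5 and percentile 90.6. The remaining named regions, 8 per sequence, had median percentiles from 80.5 to 89.8.

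A fixed list of abundant native genes served as a reference, and their folds varied. The glycolytic genes TDH3, PGK1 and CDC19 had median folds of 49.7, 50.0 and 49.4, and the histone gene HTB1 49.9, all near the ceiling. The proton pump gene PMA1 had 13.3 and the tubulin gene TUB1 15.9. Of the 16 genes of this list, 15 had a start peak in all 8 libraries, and ACT1, encoding actin, had none in any library. A raised local background lowers the fold, and 95.5% of insert peaks had one in YAC and 56.6% in integrated libraries. Among native peaks the shares were 20.8% and 20.9%, so a rank by fold is lowered more for synthetic peaks. The median synthetic peak ranked at the 48.9 ± 3.96 percentile of native peaks by fold (SD, n = 8; exact p = 0.461). Its rank was 83.3 among native peaks outside gene starts (exact p = 0.00781), and 59.1 when peaks were ranked by −log10 p (exact p = 0.109). Ranked by recovered summit pileup, an alternative chosen after seeing the data, it was 66.0 (exact p = 0.0234). Means by pileup were 79.6 ± 3.75 in YAC and 52.5 ± 3.23 in integrated libraries (SD, n = 4 each). The ranked peaks included 10 to 15 vector peaks in each YAC library and 0 or 1 in each integrated library.

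The strands of the synthetic contigs were compared with an even share. On synHPRT1 51.9% ± 1.57 of peaks were on the forward strand (SD, n = 4; exact p = 0.125), and on synHPRT1R 49.0% ± 1.73 (n = 4; exact p = 0.5). The native share was 52.3% to 56.0%. The genome-wide background was 41.0 to 52.7 in forward lists and 67.1 to 94.8 in reverse lists. Peaks of the strands were thus called at unlike sensitivity, and these shares do not measure the balance of transcription. Within libraries the synthetic share was lower than the native one in 8 of 8, by a mean difference of -4.21 ± 2.61 percentage points (SD, n = 8; exact sign-flip p = 0.00781, a comparison chosen after seeing the data). The mean difference was -2.51 points for synHPRT1 and -5.90 for synHPRT1R (n = 4 each). Per library, exact 95% Clopper-Pearson intervals of the synthetic share ran from 37.4% at the lowest bound to 63.7% at the highest, and each included the native share.

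The second comparison set the forward sequence against the reversed one. Their densities differed by less than the spread between libraries: synHPRT1R minus synHPRT1 was -0.02 on the log2 scale (exact permutation p = 0.914, 4 against 4 libraries). The direction turned, to 0.0063, with the insert alone (exact p = 0.943). Across 100 bins of 1000 bp, peak numbers of the sequences at mirrored positions had a Pearson r of 0.233 and a Spearman rho of 0.266. Of 100 circular shifts, 2 gave an r as large, the real one included (one-sided permutation p = 0.02), and 1 gave a rho as large. Without mirroring r was 0.172, which 11 of the shifts reached. In bins of 2000 bp the order turned, with an r of 0.333 mirrored and 0.352 unmirrored, which 2 of 50 shifts reached, so a relation particular to mirrored positions was not shown. Bins are not independent replicates.

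Among native genes, TRI1, TRM13, AXL1 and TAX4 had a start peak in all 4 synHPRT1 libraries and in no synHPRT1R library. PAF1, REX4, PRP21, SFT1, GTT2, SHS1 and RPS10A had the reverse. AXL1 encodes a protease of a-factor maturation, PAF1 a transcription elongation factor, SHS1 a septin and RPS10A a ribosomal protein. At a −log10 q of at least 10, 5 of these 11 genes still separated the sequences, and 8 with the peak summit inside the window. A count of 11 genes or more came from 9 of the 35 splits of the libraries, the real one included, and the median of the other splits was 8. No gene passed Fisher's exact test after adjustment (lowest adjusted p = 1), and 11 had an unadjusted p of 0.0286, the smallest possible.

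**Figure D2:**
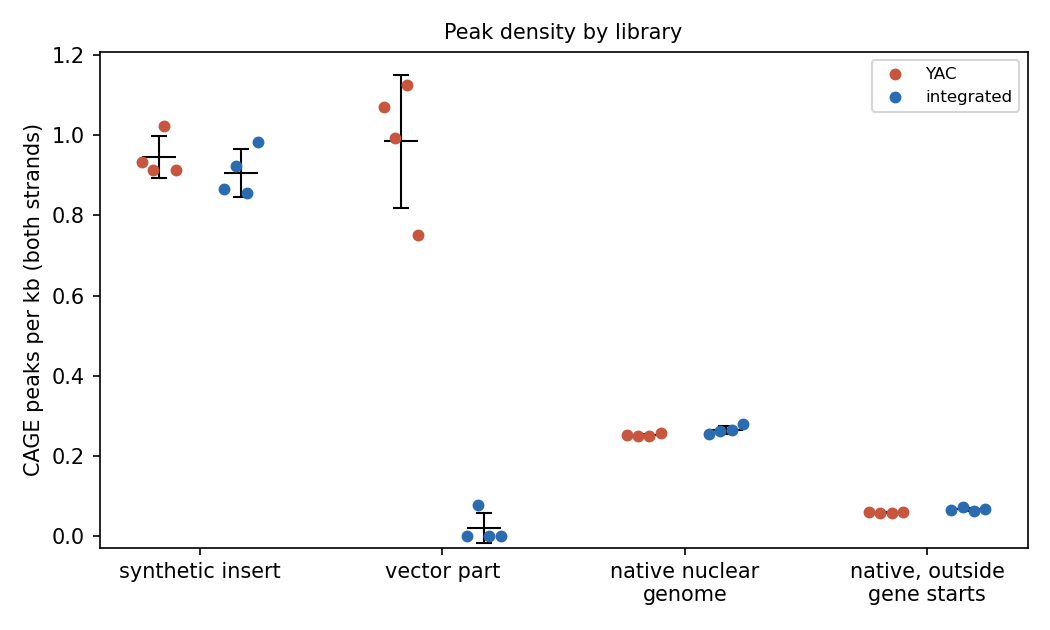
CAGE peaks per kb on both strands (y axis) for the insert, the vector, the native nuclear genome and native DNA outside gene starts, with 1 point per library and bars for mean ± SD of 4 libraries of a context. Insert density lies between 0.855 and 1.02 in all libraries, above the native density of 0.248 to 0.279.

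The third comparison set the YAC against the integrated copies, which also differed in medium. The vector part held 13 ± 2.16 peaks in YAC libraries (SD, n = 4) and 0.25 ± 0.5 in integrated ones (n = 4). The contig-to-native log2 ratio was 1.93 ± 0.10 in YAC and 1.60 ± 0.07 in integrated libraries (SD, n = 4 each), a difference of 0.32 (exact permutation p = 0.0286). With the insert alone, an alternative chosen after seeing the data, the difference was 0.14 (exact p = 0.0286). For the insert alone the call was lost with native lists of equal length (0.11, exact p = 0.0857) and, separately, without dividing by the native density (0.06, exact p = 0.343). The sequence difference depended on context by 0.06 (exact permutation p = 0.889, 36 arrangements), less than the spread between libraries. The permutation moved context labels within each sequence, so the difference between contexts widened the range it was compared with. An interaction is therefore not excluded by this p.

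SNZ1 and SNO1, neighbours in vitamin B6 synthesis, ARG1 of arginine synthesis, LEU2 of leucine synthesis, PHM7 and CFD1, an iron-sulfur cluster assembly gene, had a start peak in 4 of 4 YAC and 0 of 4 integrated libraries. Median folds in the YAC libraries were 45.9 for SNZ1 on chromosome XIII at 458408 to 459301, 27.7 for LEU2 on chromosome III at 91324 to 92418, and 20.9 for ARG1 on chromosome XV at 219211 to 220473. Whether the LEU2 peak comes from that locus or from the YAC vector was not tested. In the opposite direction stood HAM1, CYC8, NIP100, TBS1 and YDL129W, of which CYC8 encodes a general corepressor and NIP100 a dynactin subunit. HAM1 had the highest median fold of these, 6.45. A count of 11 or more came from 9 of the 35 splits, the real one included, with a median of 8 in the others. None of the 11 genes with an unadjusted p of 0.0286 passed Fisher's exact test after adjustment (lowest adjusted p = 1). With a peak in at least 3 of 4 against at most 1 of 4 libraries the count was 286 genes, which no other split reached, the highest giving 282.

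**Figure D3:**
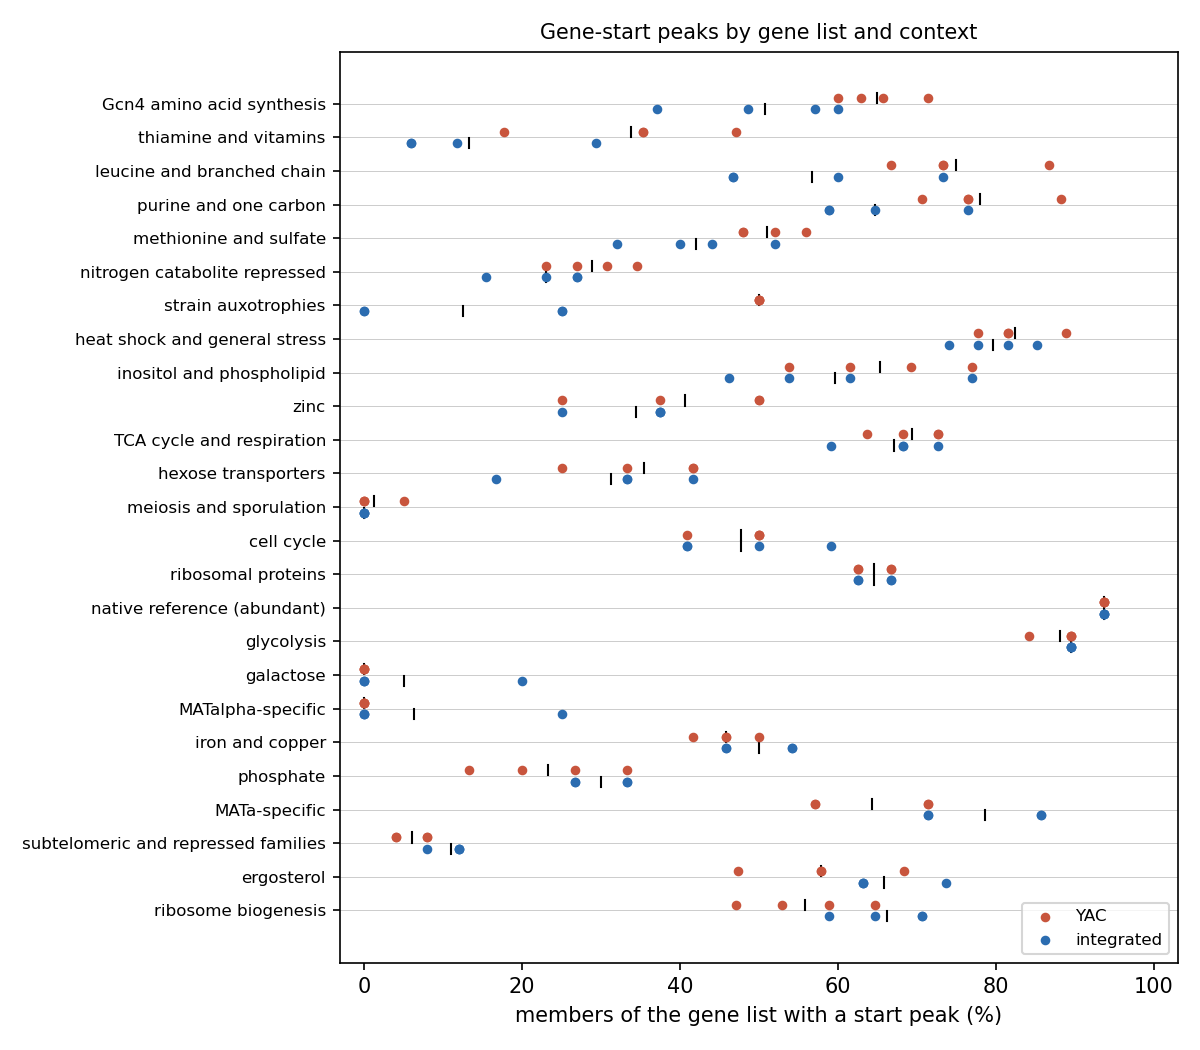
Share of each fixed gene list with a start peak in percent (x axis), with 1 point per library coloured by context and a black mark at the mean of 4 libraries. The Gcn4 amino acid list had a mean of 22.8 members with a start peak in YAC and 17.8 in integrated libraries.

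Among the 25 gene lists, that of amino acid genes under the activator Gcn4 held 2 of the 6 genes present in YAC libraries alone, SNZ1 and ARG1, among 16 members with a start peak in 1 to 7 libraries (Fisher's exact test, adjusted p = 0.0238 over 50 tests). The call was lost against the 307 genes with a start peak in exactly 4 libraries, the only ones that could separate, of which 5 are members (adjusted p = 0.156 by Fisher's exact test, a background chosen after seeing the data). SNZ1 acts in vitamin B6 synthesis. By the same Fisher's exact test it was kept with all genes with a start peak as background (adjusted p = 0.0353), at a −log10 q of at least 10 (adjusted p = 0.0288) and with at least 3 of 4 against at most 1 of 4 libraries (adjusted p = 0.0383). Of the 8 libraries left out in turn, only the omission of synHPRT1R integrated replicate 2 kept it (adjusted p = 4.83e-05 by Fisher's exact test), and with each of the other 7 left out its adjusted p was 0.0615 to 0.253 by that test. The mean number of members with a start peak was 22.8 ± 1.71 in YAC and 17.8 ± 3.59 in integrated libraries (SD, n = 4 each; exact permutation p = 0.0571, adjusted p = 0.446). Of members named after their values were seen, HIS4 had a start peak in 4 YAC and 1 integrated library, and ASN1, ARG4 and LYS4 in all 8. For thiamine and vitamin genes the means were 5.75 ± 2.06 and 2.25 ± 1.89 (exact p = 0.0571, adjusted p = 0.446), for leucine and branched-chain genes 11.2 ± 1.26 and 8.5 ± 1.91 (exact p = 0.114, adjusted p = 0.446). Purine and one-carbon genes had 13.2 and 11.0, and methionine and sulfate genes 12.8 and 10.5. Ribosome biogenesis genes had 9.5 and 11.2, ergosterol genes 11.0 and 12.5, and ribosomal proteins 15.5 in both. LEU2, whose peak may stem from the YAC vector, counts in the leucine list and in the auxotrophy list. The auxotrophy list, with 2 and 0.5 members, was the only one at the smallest exact permutation p of 0.0286 between contexts. Adjusted over 25 lists, that p could pass only if most lists reached it, and the lowest adjusted p was 0.446. Adjusted over the list alone, 0 genes of any list passed in either comparison, but with a smallest Fisher's exact p of 0.0286 a gene could pass only if most of its list separated.

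Genes that check the strain labels were examined one by one. LEU2, of which the strain's own genome lacks a working copy, had a start peak only in YAC libraries, MET17 and URA3 in 0 of 8 libraries, and HIS3 in 4 YAC and 2 integrated libraries. Of mating-type a genes, the pheromone genes MFA1 and MFA2, the exporter gene STE6 and AGA2 had one in all 8 libraries, ASG7 in 6, STE2 in 2 and BAR1 in 0. Of the alpha genes, MF(ALPHA)1 had one in 1 library, and MF(ALPHA)2, STE3 and SAG1 in 0. Of 20 meiosis and sporulation genes, 19 had none. Near the insertion point on chromosome XI, the cell wall gene PIR1 at 141794 to 142819 had a start peak in 8 libraries and PIR3 at 144401 to 145378 in 4 YAC and 2 integrated libraries, both synHPRT1. YKL162C and KDX1 had none.

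Overlap between libraries showed how far the lists recur. Replicate pairs shared 50.7% of native peaks by the Jaccard index (range 48.6% to 51.9%, 4 pairs), and pairs of libraries that differed in sequence and context 49.6% (8 pairs). On the synthetic contig replicate pairs shared 58.7% (4 pairs), and pairs of one sequence in different contexts 48.3% (8 pairs). On the insert alone, without the vector, these values were 60.0% and 53.7%, and the difference was not tested.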

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

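No test was planned for the vector and mitochondrial peaks given here. The vector part, absent from the integrated genome by the placement of the insert, held 1 peak in synHPRT1 integrated replicate 2. Mitochondrial DNA, which the densities left out, held 5 peaks in synHPRT1 YAC replicate 1, 5 in replicate 2, 2 in synHPRT1 integrated replicate 1, 4 in replicate 2, 4 in synHPRT1R YAC replicate 1, 3 in replicate 2, 5 in synHPRT1R integrated replicate 1 and 4 in replicate 2. Dixon's test, run on measures of the comparisons above, singled out no library in 40 sets of values. Each set held the 4 libraries of a context, the 4 of a sequence or all 8, since groups of 2 cannot be tested. Sets of a sequence and of all 8 mix the contexts, which can hide an outlying library.

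The tests of the next 3 patterns, on the vector, the native lists, the recovery of the pileup and the splits of the libraries, were chosen after their results were seen, and the comparison on the same genes and regions was set before. YAC libraries had a higher synthetic-to-native density than integrated libraries, by 0.32 on the log2 scale. Absence of the vector from the integrated strains is not the whole source, because the insert alone still differed by 0.14 (exact p = 0.0286). With equal list lengths the contig still differed by 0.31 (exact p = 0.0286). The contig includes the vector, so this setting cannot tell what part longer native lists in the integrated libraries play. The insert-alone difference was 0.115 (exact p = 0.0857) with native lists of equal length and 0.0626 (exact p = 0.343) undivided. Whether the vector and longer native lists together account for the whole difference stays open. Medium was not separable from context.

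Synthetic peaks ranked higher by recovered summit pileup in YAC libraries, at the 79.6 percentile ± 3.75 of native peaks against 52.5 ± 3.23 (SD, n = 4 each; exact p = 0.0286). With labels moved within each sequence the exact permutation p was 0.0556, the smallest that 36 arrangements allow. Vector peaks were included in these ranks. Different peak calls in the contexts were argued against: with the same 1239 native genes and the same insert regions in every library the difference was 45.6 points (exact p = 0.0286). The direction did not depend on recovery of the pileup, since the deposited fold gave a difference of 6.50 points (exact permutation p = 0.0286). The recovered pileup, solved in part from that fold, gave 27.1 points. What part of that size comes from the recovery cannot be told from the fold. Of insert peaks, 95.5% had a local background above that of the genome in YAC and 56.6% in integrated libraries, which lowers their folds. The shares of native peaks were 20.8% and 20.9%. A higher copy number of the YAC and an effect of SC-Leu on native genes may each account for the higher rank, and neither was tested.

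The 11 genes separating the contexts and the 11 separating the sequences were each equalled or exceeded in 9 of the 35 splits, and the highest other split gave 19 genes. Chance cannot be excluded for either count. For the contexts the share of splits moved with the setting. At a −log10 q of at least 10, 2 of the 35 splits gave as many (15 genes), and with equal list lengths 16 did (10 genes). With at least 3 of 4 against at most 1 of 4 libraries, only 1 did (286 genes). LEU2 was among the genes separating the contexts. The strain's own genome lacks a working copy, and YAC strains were grown in SC-Leu. Its peak may therefore stem from a marker gene on the YAC vector and not from chromosome III, which was not tested.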

How the results depend on the processing

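Alternatives with the insert alone, the recovered pileup or the native strand share, the background of genes in exactly 4 libraries, and each library left out of the list enrichment, were chosen after seeing the data. The synthetic-to-native ratio (1.72 to 2.15 on the log2 scale over all alternatives) and the ratio to DNA outside gene starts (at least 3.89 over the settings, 3.78 to 3.87 with each library left out) kept their direction in every one and their call in each that had a test. The replicate block gave the first no test. Counting every line changed nothing, since no interval was listed more than once. The difference between sequences had no stable direction: 0.0540 at a −log10 q of at least 10, 0.00176 with equal list lengths, 0.00629 with the insert alone, 0.0248 with the insert from the other reference, 0.0260 undivided, 0.0514 for the insert undivided, 0.0279 and 0.0318 for the insert with equal total or native list lengths, and -0.12 to 0.0609 with each library left out. The lowest exact p of these was 0.371. The interaction lay between -0.0642 and 0.19 with each library left out, and turned without replicate 1 of synHPRT1R YAC or of synHPRT1R integrated. The cause was not tested. The YAC difference stayed at 0.32 in a replicate block and within levels of the other factor (exact p = 0.0556 in both, the smallest that 36 arrangements allow, so the loss of the call follows from the construction). It was 0.28 to 0.36 with each library left out and lost its call for the insert undivided (0.0626) and for the insert with equal total (0.120, exact p = 0.0571) or native list lengths (0.115, exact p = 0.0857). The correlation of deviations between same-numbered libraries lay between -0.05 and 0.02, so the numbers showed no pairing. A replicate block cannot change either count of 11 genes, only the splits compared, of which 7 of 18 balanced ones were as large. The rank of synthetic peaks moved from 48.9 to 59.1 by −log10 p, 83.3 outside gene starts, 66.0 by recovered pileup and 89.3 by pileup outside gene starts. With at least 3 of 4 against at most 1 of 4 libraries, 286 genes separated the contexts and 237 the sequences, where 1 and 20 of the 35 splits gave as many. With each library left out the counts were 20 to 33 and 13 to 35, larger because 3 of 3 is met more easily, and 0 to 1 gene lists passed. With genes in exactly 4 libraries as background, 0 lists passed. The strand difference from native peaks was -3.97 points with the insert alone and -4.88 with the stricter q, lower in 7 and 6 of 8 libraries (exact p = 0.0234 and 0.0312). With a reciprocal overlap of 50%, replicates shared 47.0% of native and 45.2% of synthetic peaks, and with the stricter q 54.2% of native peaks. Depth, unknown as a count, limits any statement on absent peaks.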

Other observations

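The counts at noncoding RNA genes and the test at the insertion point were chosen after the data were seen, as were the counts with sequence copies merged. The splits of native peak regions were set before their result. Start peaks stood in all 8 libraries at TLC1, the telomerase RNA gene, at SCR1 of the signal recognition particle, and at the spliceosomal RNA genes LSR1 and SNR19. SNR6, SNR14 and both annotated forms of SNR7, also spliceosomal RNA genes, had none in any library. Of 76 small nucleolar RNA genes 4 had one in all 8 libraries (SNR10, SNR30, SNR37 and SNR86) and 54 in none. Of 275 nuclear tRNA genes, 268 had none. Whether the peaks at noncoding RNA genes mark capped 5′ ends was not tested.

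Native peak regions, counted per strand, separated the contexts at 24 of 6963 positions, 10 in YAC and 14 in integrated libraries alone. Only 1 of the 35 splits reached that count, the real one, and the highest other gave 21. Some of these regions are copies of one sequence. With regions that share sequence counted once, 19 separated the contexts, 3 of the 35 splits gave as many, and the highest other gave 22. Leaving out LEU2 as well gave 18, again with 3 of the 35 splits as large and 22 in the highest other. Chance can therefore not be excluded. Among the 24 regions, 1 lay within 1000 bp of the insertion point, on the minus strand of chromosome XI at 145916 to 146282, with summits 251 to 347 bp to the left of it and folds of 3.69 to 12.0 in the 4 integrated libraries. If the 24 regions lay at random positions, at least 1 would fall there with a probability of 0.00397, a value computed for a region picked out after the data were seen. What gives rise to this peak was not tested.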
